A study of Drosophila melanogaster with 12 samples.

How the data were processed

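Polyadenylated RNA from dissected gonads of flies 1 to 3 days old, raised at 25 °C, was isolated and 200 ng per library was prepared with an Illumina TruSeq RNA v2 kit, which does not mark strand, per the labels' protocols. The deposited values are whole-number counts of reads per gene in 1 file per library. Per the submitters' processing notes, the tools were FastQC, Bowtie2 2.2.9, TopHat2 2.1.1, HTSeq 0.9.1 and DESeq, on genome build BDGP6; the strand and overlap settings and the annotation release are not given in the sources used here. The deposited counts carry HTSeq's 5 summary lines, which were left out of library sizes and tests. They held between 12.0% and 17.1% of the reads of a library, of which those on no annotated feature were between 0.503% and 1.02%.

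Symbols were matched to 17253 of 17559 gene IDs, and 306 had no match. Gene positions and transcript lengths came from an Ensembl annotation of BDGP6, whose release may differ from the one used for counting. No genome sequence was used, so base composition was not examined.

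Groups were taken from the sample titles. The titles give replicate numbers, and the labels call the replicates biological. Within each group every pair of libraries differed beyond counting noise, with a chi-square per degree of freedom of at least 9.32, so all 12 were kept as separate replicates. The total depth of 16152230 to 25097969 assigned reads sets the counting precision: 3 counts were used as the floor where a group had none, and floors and Wilson 95% intervals of shares cover counting error only.

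Each comparison was fitted on its own 6 libraries with edgeR 4.0.16 in R 4.3.3, using trimmed mean of M values scaling, filterByExpr, robust dispersions and the quasi-likelihood F test, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Comparisons were bam testis over bam ovary, Sxl RNAi over mCherry RNAi ovary and, as background, mCherry RNAi over bam ovary. The SE of a log2 fold change was its size divided by the square root of F. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation as an alternative, and with fry. Adjusted list p-values cover all lists of a comparison. Of 423 list entries, 400 matched a gene ID. The difference between the sex effect and the Sxl effect, and Sxl RNAi over bam ovaries, were contrasts in an edgeR fit to all 12 libraries. For single genes picked out from their values, p-values of the contrast with bam ovaries and of the background comparison were also adjusted by Holm's method over all genes tested.

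The main tests, gene lists and alternatives were set before the data were examined. Named genes followed a rule set then: Sxl, CG15930, Phf7, bam and msl-2; the 8 largest changes in each direction with an adjusted p under 0.05, no overlap of CPM between groups and a mean of at least 5 CPM in the higher group; up to 4 members of each list with the smallest p; and up to 10 genes changed in the same direction in both main comparisons. For the background comparison it took 4 genes per direction. Members of near-identical families are given only as a family.

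Alternatives were DESeq2 1.42.0, relative log expression and upper-quartile scaling, no filter, a filter at 1 CPM in 3 libraries, all 12 libraries in one fit, an absolute log2 fold change over 1, the replicate number as a block, and leaving out each replicate. After the data were seen, removal of a trend on transcript length and the omission of 1 library per group were added.

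The scripts were tested on simulated counts drawn from the real means, library sizes and dispersions, with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were picked among those with a mean of at least 5 CPM, and counts of different genes were drawn independently. In the sex comparison (9587 genes) 36% of the 2-fold and 90% of the 4-fold changes were recovered, with 8 false calls among 134. In the RNAi comparison (9904 genes) these were 72% and 99%, with 9 false calls among 180, and in the background comparison (9831 genes) 53% and 100%, with 9 among 162.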

Results

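RNA was measured in gonads of Drosophila melanogaster carrying mutations in bam, the gene that lets germ cells leave the stem cell state and differentiate, so that early germ cells accumulate in these gonads. The 12 libraries fell into 4 groups of 3 biological replicates. These were ovaries of bam females, testes of bam males, and ovaries of bam females with RNA interference (RNAi) against either Sxl or mCherry. Sxl encodes the RNA-binding protein that sets female identity, and mCherry is absent from the fly genome, so its knockdown serves as the control. Reads assigned to genes numbered 20258167, 16517104 and 19116790 in bam ovaries and 17370254, 16152230 and 18021046 in bam testes. They numbered 25097969, 24274511 and 21501840 in mCherry RNAi ovaries and 16570573, 23411755 and 17654077 in Sxl RNAi ovaries. Levels are in CPM, counts per 1000000 reads assigned to genes after scaling, given as mean ± SD with n = 3, and fold changes carry the standard error (SE) of the log2 value. Adjusted p-values of genes are from the quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment.

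The first comparison asked which transcripts differ between male and female gonads arrested by loss of bam. Testes held far more RNA of CG15930 (FBgn0029754), also named Tdrd5l, which encodes a Tudor-domain protein and is the subject of the series. It stood at 422 ± 26.9 CPM in testes and 24.2 ± 3.89 CPM in ovaries, a log2 fold change of 4.12 (SE 0.18, adjusted p = 4.58e-05). Phf7 (FBgn0031091), a male germline chromatin reader, was 4.16-fold higher in testes (281 ± 19.8 against 67.4 ± 5.67 CPM, adjusted p = 0.000142). Sxl (FBgn0264270) was 5.51-fold lower in testes (77.6 ± 42.7 against 428 ± 51.2 CPM, adjusted p = 0.00454). Residual bam RNA was higher in testes by 1.25 on the log2 scale (SE 0.15, adjusted p = 0.00115), while msl-2, which Sxl represses in female somatic cells, gave 0.25 (SE 0.30, adjusted p = 0.578). In all, 1594 genes were higher in testes and 1592 were higher in ovaries among 9738 tested. Leaving out bam ovary replicate 1 or 2, or bam testis replicate 1, lowered the total of 3186 genes to 2000, 1924 and 2056.

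Genes of follicle cells, yolk and eggshell formed the group with the lowest list p-value. Of 16 members tested, 14 were lower in testes and none was higher (15 lower when adjusted over the list alone; camera adjusted p = 1.94e-18, and adjusted p = 0.0774 with an estimated correlation). The yolk protein gene Yp1 stood at 722 ± 54.2 CPM in ovaries and 0.534 ± 0.142 CPM in testes, and the vitelline membrane gene Vm26Aa at 751 ± 91.7 and 0.465 ± 0.275 CPM. Among oocyte and maternal genes, 7 of 20 were lower in testes (10 adjusted over the list alone; camera adjusted p = 0.00839, and adjusted p = 0.816 with an estimated correlation). They included osk, which directs germ plasm assembly (log2 fold change -3.70, SE 0.33), and bcd, the anterior determinant (-1.99, SE 0.41). This list's adjusted p rose to 0.0657 without bam testis replicate 2 and lay between 0.00449 and 0.816 over 12 alternatives. Of 24 piRNA pathway genes tested, 4 were lower and 1 was higher in testes (the same numbers adjusted over the list alone; camera adjusted p = 0.244). The lower ones included piwi (-1.54, SE 0.21) and armi (-1.72, SE 0.23), and the higher one was zuc (0.86, SE 0.15).

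Of 7 members of the male dosage compensation complex, 3 were higher in testes, also when adjusted over the list alone. These were the noncoding RNAs roX1 (139 ± 17.1 against 0.726 ± 0.189 CPM) and roX2 (6.88 ± 2.05 against 0.604 ± 0.157 CPM), and msl-3 (log2 fold change 0.77, SE 0.14). The list gave a camera adjusted p of 0.0230, with an adjusted p = 0.561 under an estimated correlation 0.0501 without bam ovary replicate 3 and between 0.000306 and 0.561 over 12 alternatives. Of 9 early male germline genes, CG15930, Phf7 and tut were higher in testes, 3 also when adjusted over the list alone (camera adjusted p = 0.0535). That adjusted p lay between 0.00360 and 0.455 over 12 alternatives. It was 0.0366 and 0.0453 without bam ovary replicates 1 and 2, 0.0377 and 0.0155 without bam testis replicates 1 and 2, and 0.0499 with relative log expression scaling. CG15930 was in this list because the series is about it, so its count is not independent evidence of direction. Of 12 spermatocyte genes, 5 were higher and 2 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.453), among them nht, a testis-specific TAF (3.98, SE 0.38). Of 6 spermatid and sperm genes tested among 27 listed, Mst87F was higher, with 2 counts in the ovaries together (camera adjusted p = 0.915). The only Y-linked gene of the list that was tested, FDY, stood at 57.3 ± 9.40 CPM in testes and 0.0988 ± 0.0861 CPM in ovaries (camera adjusted p = 0.00491, and adjusted p = 0.236 with an estimated correlation).

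Somatic genes differed in both directions. Of 16 genes of the ovarian terminal filament, cap and escort cells, 4 were higher and 6 lower in testes (5 and 8 adjusted over the list alone; camera adjusted p = 0.627), with ptc, the Hedgehog receptor, lower (-2.01, SE 0.30) and GstS1 higher (4.71, SE 0.23). Of 14 genes of testis hub and cyst cells, 4 were higher and 7 lower (4 and 8 adjusted over the list alone; camera adjusted p = 0.0789, and adjusted p = 0.0319 without bam ovary replicate 3, between 0.00812 and 0.893 over 12 alternatives), with tj, a factor of gonadal somatic cells in both sexes, lower (-3.02, SE 0.21). Genes listed beforehand as markers of tissue outside the gonad also differed by sex. Whether their RNA came from outside tissue or from the gonad itself was not tested. Of 24 genes of the male accessory gland and ejaculatory duct, 22 were higher in testes (22 adjusted over the list alone; camera adjusted p = 2.55e-05, and adjusted p = 0.816 with an estimated correlation). In the comparisons of ovaries alone, 1 of the 27 listed genes passed the filter on low counts. Most of the 24 thus entered this test through the testes, which fixed their direction. Their count and list p-value are therefore no independent evidence of that direction. Bam testis replicate 2 held most of this accessory gland RNA. Acp36DE, a seminal fluid protein gene, stood at 738 CPM there against 78.9 and 33.2 CPM in replicates 1 and 3. These genes took 0.0658% (95% Wilson interval 0.0646% to 0.0670%), 0.412% (0.409% to 0.416%) and 0.0314% (0.0306% to 0.0323%) of the counts in testis replicates 1, 2 and 3, and at most 0.00276% in bam ovaries. Such intervals cover counting error only. Of 19 muscle genes, 16 were lower in testes and 1 was higher (16 and 1 adjusted over the list alone; camera adjusted p = 1.36e-11, and adjusted p = 0.236 with an estimated correlation), and muscle genes took between 1.04% and 1.49% of the counts in bam ovaries and between 0.193% and 0.219% in testes. Hemocyte genes (5 of 12 lower, 1 higher; 6 and 1 adjusted over the list alone; camera adjusted p = 0.0244) and sperm storage organ and oviduct genes (3 of 4 lower, 3 adjusted over the list alone; camera adjusted p = 0.0244) had adjusted p = 0.816 and 0.562 with an estimated correlation. The hemocyte call was lost without bam testis replicate 2 (0.0657) or 3 (0.0613), with values between 0.00664 and 0.816 over 12 alternatives.

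**Figure D1:**
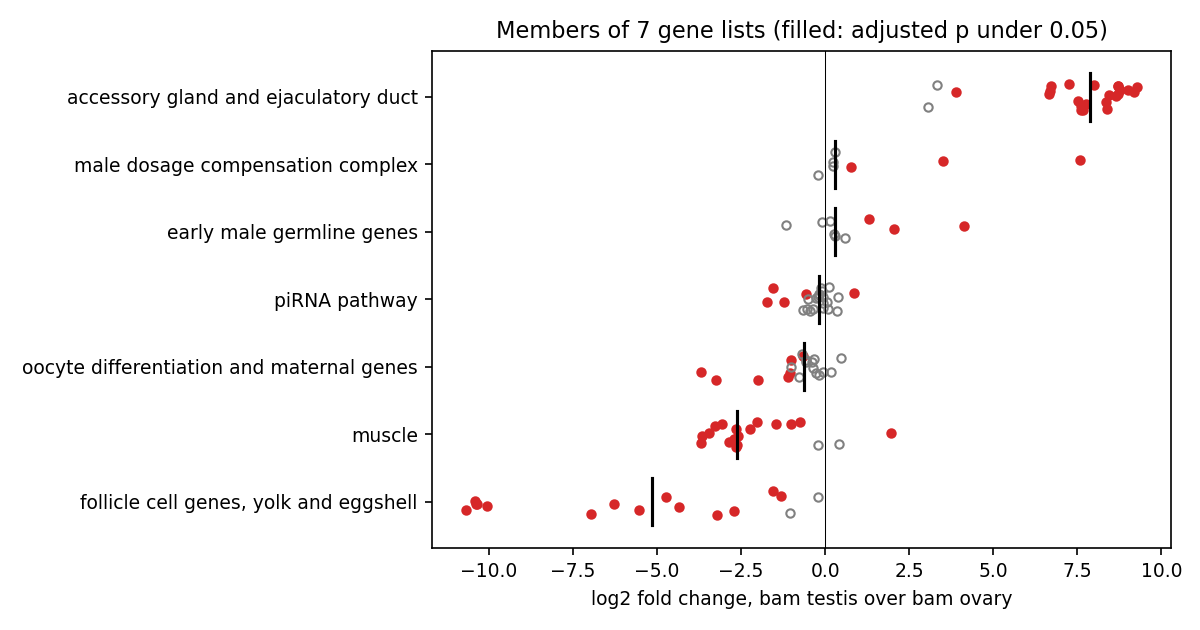
Log2 fold change of bam testis over bam ovary (horizontal axis) for the tested members of 7 gene lists (vertical axis). Each point is 1 gene, red where its adjusted p is under 0.05, and the black bars are list medians; 14 of 16 follicle cell genes lie to the left and 22 of 24 accessory gland genes to the right as red points.

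The largest fold changes that met the rule for named genes were of genes near silence in the other sex. CG7333 had no counts in bam ovaries and was at least 315-fold higher in testes (49.2 ± 12.5 CPM), with the floor set at 3 counts per library. lncRNA:CR43684 reached 1347 ± 680 CPM in testes against 0.210 ± 0.0681 CPM in ovaries. MFS9, Nep5 and CG42828 were also among the 8, whereas CG43319, Sfp51E and lectin-30A stood at 67.0, 34.8 and 89.6 CPM in bam testis replicate 2 and at no more than 2.94, 2.53 and 4.18 CPM in the others. Of these 3, CG43319 and Sfp51E no longer passed the threshold when any bam ovary or bam testis replicate 1 was left out (adjusted p up to 0.101 and 0.0865), and lectin-30A when any bam ovary was left out (up to 0.0931). In ovaries the 8 were Vm26Aa, Yp1, Yp2, Vm34Ca, Vm26Ab, CG43134, CG13299 and Osi19, of which CG43134 stood at 2466 ± 330 CPM in ovaries and 1.52 ± 0.828 CPM in testes. Osi19 had no counts in testes and was at least 76.0-fold lower there. X-linked genes as a class were lower in testes. The median log2 fold change of 1656 X-linked genes was -0.41 and that of autosomal genes was 0.10 (camera p = 1.84e-05, adjusted over the 3 comparisons 5.52e-05, and p = 0.000699 with an estimated correlation), and 472 X-linked genes were lower in testes against 188 higher. On chromosome 4, 32 of 84 genes were lower and 3 were higher.

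The remaining lists gave no camera adjusted p under 0.05 in this comparison. Higher and lower members numbered 3 and 5 of 15 sex determination genes, 2 and 2 of 6 reported Sxl targets, 3 and 2 of 15 germ cell identity genes, 1 and 1 of 15 Tudor-domain genes, and 2 and 5 of 17 meiotic recombination genes. For the same lists adjusted over the list alone they numbered 3 and 6, 2 and 3, 3 and 2, 1 and 1, and 3 and 5. They numbered 1 and 2 of 13 JAK-STAT genes, 2 and 3 of 12 fat body genes, 3 and 0 of 16 heat shock genes, 3 and 4 of 24 cell cycle genes, 1 and 2 of 11 BMP genes, and 1 and 1 of 10 neural genes. For these, adjusted over the list alone, they numbered 1 and 2, 2 and 4, 0 and 0, 3 and 4, 1 and 1, and 1 and 1. By fry, 11 lists moved on balance in one direction at an adjusted p under 0.05. These were the follicle cell (2.76e-05), Y-linked (0.000173), muscle (0.000441), dosage compensation (0.00276), early male germline (0.00276), sperm storage (0.00886), hemocyte (0.0182), Sxl target (0.0381), hub and cyst cell (0.0385), oocyte (0.0394) and spermatocyte lists (0.0434). The accessory gland list did not pass by fry (adjusted p = 0.0757). The median, the mean and the test did not all share a sign for the sex determination, Sxl target, spermatid, germ cell identity and Tudor-domain lists. Fat body genes, with a camera adjusted p of 0.0789, gave an adjusted p of 0.00210 without bam ovary replicate 1 and between 0.00210 and 0.924 over 12 alternatives. Lower members included the sex determination gene tra (-0.94, SE 0.17) and the transferrin gene Tsf1 (-4.63, SE 0.29).

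The second comparison asked which transcripts respond to loss of Sxl in female bam gonads. Sxl RNA stood at 145, 205 and 230 CPM in the 3 Sxl RNAi ovaries and at 514, 519 and 544 CPM in the mCherry RNAi ovaries, 2.72-fold lower with Sxl RNAi (log2 fold change -1.44, SE 0.18, adjusted p = 0.0466). CG15930 (X chromosome, 5315130 to 5317295 of BDGP6, minus strand) rose from 16.7 ± 2.50 to 288 ± 55.2 CPM, a log2 fold change of 4.11 (SE 0.20, adjusted p = 0.000961). Its end overlaps that of CG4198 on the other strand, which stood at 1.97 ± 0.240 against 1.37 ± 0.0751 CPM. The gain of CG15930 in Sxl RNAi ovaries and its sex difference differed by 0.04 on the log2 scale (SE 0.26, adjusted p = 0.943 for the difference in an edgeR fit to all 12 libraries). Phf7 was at 108 ± 20.1 against 69.9 ± 11.7 CPM and did not pass the threshold (0.62, SE 0.18, adjusted p = 0.255). It passed when mCherry RNAi replicate 2 and Sxl RNAi replicate 1 were both left out, a choice made after the data were seen (adjusted p = 0.0188, range over 13 alternatives 0.0188 to 0.635). Its sex difference exceeded its difference under Sxl RNAi by 1.45 (SE 0.23, adjusted p = 0.000781). The values for bam and msl-2 were 0.52 (SE 0.21, adjusted p = 0.410) and 0.37 (SE 0.16, adjusted p = 0.453).

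**Figure D2:**
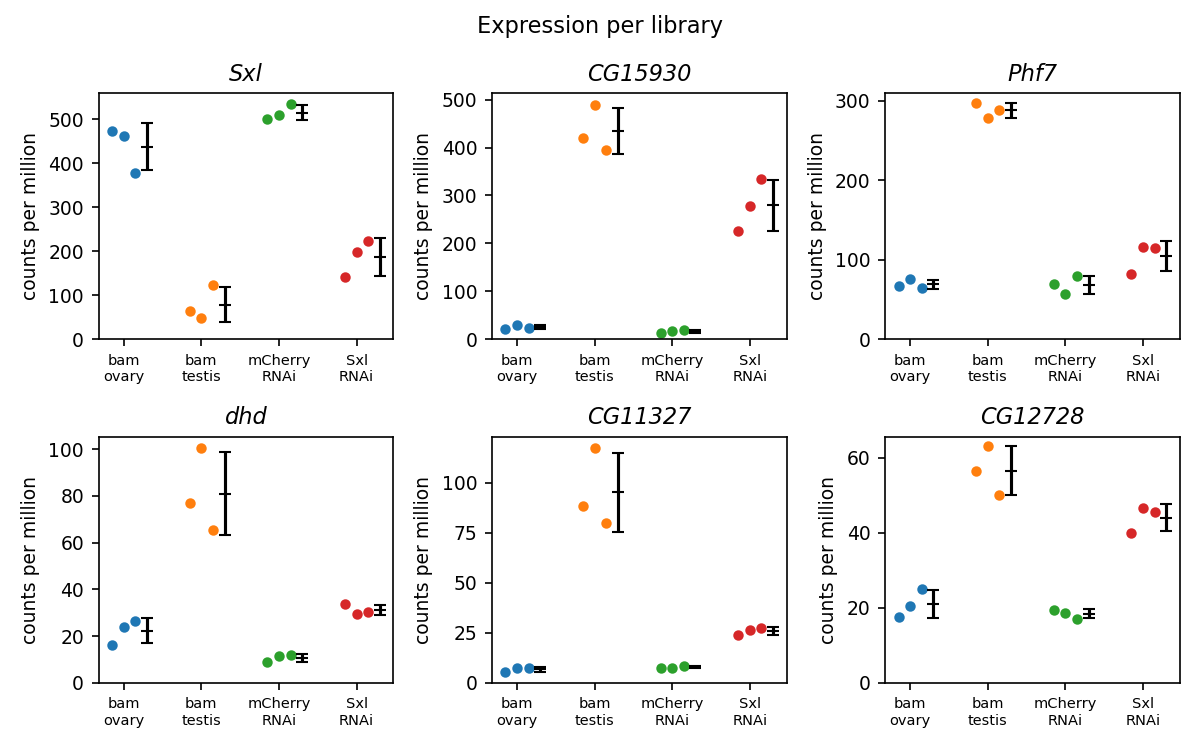
CPM (vertical axes, from 0, scaled over all 12 libraries) of 6 genes in each library of the 4 groups, with the mean and SD (n = 3) beside the points. CG15930 is high in bam testes and in Sxl RNAi ovaries and low in both control ovaries, while Phf7 is high in testes.

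In all, 12 genes were higher and 9 lower in Sxl RNAi ovaries among 10059 tested. Besides CG15930, the higher ones were dhd, a germline thioredoxin gene (32.1 ± 2.28 against 10.8 ± 1.61 CPM, adjusted p = 0.0132), Tbh, which encodes tyramine beta-hydroxylase (23.1 ± 2.35 against 7.47 ± 1.31 CPM, adjusted p = 0.0242), the anaphase-promoting complex gene APC7 (1.99, SE 0.16), CG11327 (1.74, SE 0.12), CG5568 (2.37, SE 0.28), Corp, CG12728, CG10702, Uros1, CG10802 and Cmtr1. The lower ones besides Sxl were CG30076 (0.585 ± 0.0793 against 18.4 ± 1.47 CPM), Dscam3, a cell adhesion gene (0.510 ± 0.0584 against 9.12 ± 2.75 CPM), asRNA:CR45600 and the overlapping CG6912, Cep290, scaf, EMC2A and CG7755. Of these 9 lower genes, CG30076, Dscam3, asRNA:CR45600, CG6912 and Cep290 were also higher in mCherry RNAi than in bam ovaries, while Sxl, scaf and CG7755 were also lower in Sxl RNAi than in bam ovaries. Of the 12 higher genes, CG15930, CG11327, CG12728, APC7, Uros1 and CG10702 were also higher than in bam ovaries, and for dhd, Tbh, Corp, CG5568, CG10802 and Cmtr1 that contrast did not pass the threshold. In the background comparison 5 of the 12 were lower in mCherry RNAi than in bam ovaries, namely dhd (-1.07, adjusted p = 0.0347), Corp (-0.84, adjusted p = 0.0416), CG5568 (-2.14, adjusted p = 0.0131), Cmtr1 (-0.54, adjusted p = 0.0485) and APC7 (-1.10, adjusted p = 0.0249). Reads of asRNA:CR45600 and CG6912 cannot be told apart where they overlap, because the library kit does not mark strand. Uros1 and CG10702 fell outside the rule for named genes and are listed to complete the count. DESeq2 called 296 genes, including all 21. Leaving out mCherry RNAi replicate 1 or 3, or Sxl RNAi replicate 2 or 3, left 3, 4, 3 and 3 genes, each time with CG15930, CG30076 and asRNA:CR45600 among them. CG15930 passed the threshold under all 13 alternatives run for it, with log2 fold changes between 3.96 and 4.28, whereas Sxl passed under 6 of 13, with values between -1.59 and -1.27 and adjusted p up to 0.238. The Sxl call was lost without any 1 of the mCherry RNAi replicates (adjusted p = 0.190, 0.0864 and 0.162), without Sxl RNAi replicate 2 (0.238) or 3 (0.117), and in the fit to all 12 libraries (0.0872).

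Of the 12 higher genes, 9 were X-linked, against 17.0% of all genes tested (Fisher's exact test, two-sided, p = 1.57e-05), and Sxl was the only X-linked gene among the 9 lower ones. This test was chosen after the pattern was seen in the same genes. It also takes genes as independent, although dhd and CG15930 lie close together (starts at 5312171 and 5315130). All 9 X-linked higher genes lay between positions 3482965 and 8900264, a segment of 5.42 Mb that holds 410 of the 1711 X-linked genes tested. Over all X-linked genes the median log2 fold change was 0.050 (camera p = 0.0158, adjusted over the 3 comparisons 0.0236, and p = 0.160 with an estimated correlation). At the preset correlation the camera p was 0.189 without mCherry RNAi replicate 2 and 0.187 without Sxl RNAi replicate 3.

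**Figure D3:**
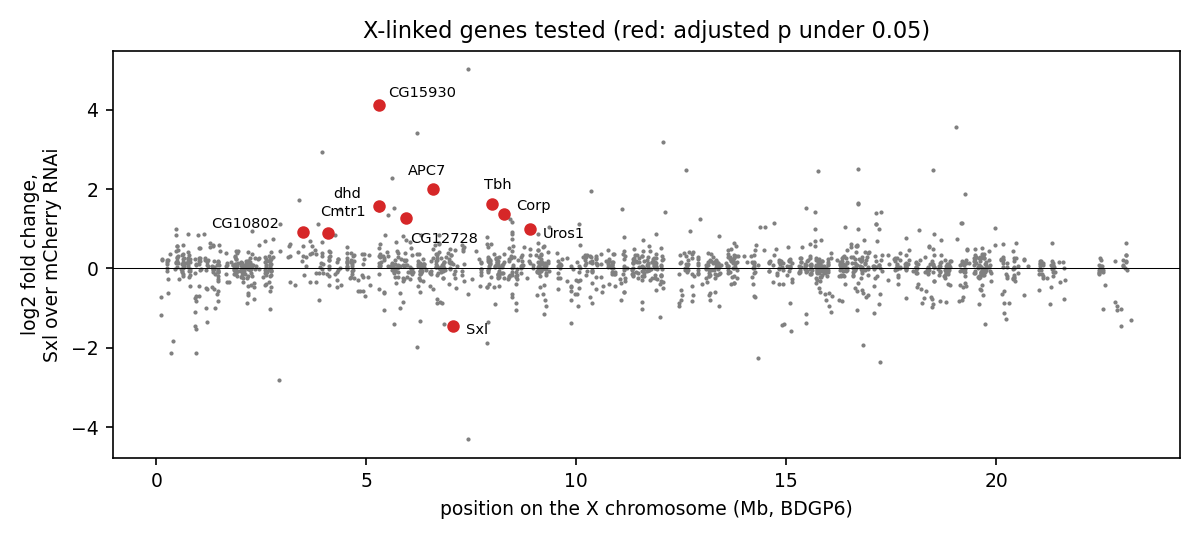
Log2 fold change of Sxl RNAi over mCherry RNAi ovaries (vertical axis) against position on the X chromosome in Mb (horizontal axis) for each of 1711 genes tested. Red points have an adjusted p under 0.05; the 9 higher ones lie in a segment of 5.42 Mb that also holds Sxl.

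The male dosage compensation list was higher in Sxl RNAi ovaries by its list test, with no member past the threshold over all genes and 3 of 7 adjusted over the list alone (camera adjusted p = 0.00213, and adjusted p = 0.920 with an estimated correlation). Its members mof, msl-3 and roX1 gave 0.83 (SE 0.15), 0.43 (SE 0.10) and 1.11 (SE 0.36). Of these, mof and roX1 lie in the X segment of 5.42 Mb described above, whereas msl-3 lies on chromosome arm 3L. Early male germline genes had 1 of 9 higher, CG15930, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00346, and adjusted p = 0.920 with an estimated correlation). Reported Sxl targets had 1 of 6 higher and 1 lower, 2 and 1 adjusted over the list alone (camera adjusted p = 0.0318, and adjusted p = 0.999 with an estimated correlation). Both of these lists hold CG15930, which gave 4.11, and were not chosen independently of the series. The early male germline list had a mean log2 fold change of 0.45 and a median of 0.099. For reported Sxl targets these were 0.62 and 0.32, and the lower member was Sxl, the target of the RNAi itself. Neither list was tested without CG15930, so neither list test shows a rise of the other members. Without mCherry RNAi replicate 2 the adjusted p of these 3 lists rose to 0.154, 0.480 and 0.480. Over 12 alternatives it lay between 6.89e-05 and 0.920, 3.01e-08 and 0.920, and 3.09e-07 and 0.999. Heat shock genes were lower by the list test (0 of 16 past the threshold, also adjusted over the list alone; camera adjusted p = 0.000180, and adjusted p = 0.999 with an estimated correlation). Their RNA took 3.19% (95% Wilson interval 3.18% to 3.20%) of the counts in mCherry RNAi replicate 1 and between 0.565% and 1.18% in the other RNAi libraries, and without that replicate the adjusted p was 0.184, the range over 12 alternatives being 8.07e-26 to 0.999. No other list gave a camera adjusted p under 0.05 with all 6 libraries. Some did when 1 library was left out. Sex determination and Tudor-domain genes gave 0.000743 without Sxl RNAi replicate 1, fat body genes 0.000174 without that replicate and 0.00356 without mCherry RNAi replicate 1, and piRNA pathway genes 0.0394 without Sxl RNAi replicate 2. The highest value over 12 alternatives was 0.999 for each of these lists, and their lowest values were those given. Sex determination genes gave 0.00460 in the fit to all 12 libraries. By fry no list passed the threshold in this comparison, with adjusted p = 0.152 for dosage compensation, early male germline and Sxl target genes and 0.776 for heat shock genes. In particular, 0 of 22 follicle cell, 0 of 20 oocyte, 0 of 24 piRNA pathway, 0 of 11 spermatocyte and 0 of 6 spermatid genes passed the threshold, with 0, 2, 0, 1 and 0 adjusted over the list alone. The tests of this comparison called 1172 genes at an unadjusted p under 0.05.

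The third question was whether genes that differ by sex respond to Sxl. No library was shared between the comparisons. Of 9415 genes tested in both, 6 were higher in testes and in Sxl RNAi ovaries, where independent lists of 1371 and 12 genes would share 1.75 (Fisher's exact test, two-sided, p = 0.00396). These were CG15930, CG11327, dhd, CG12728, CG10802 and Cmtr1, all but CG11327 in the X segment described above. For dhd, CG10802 and Cmtr1 the contrast with bam ovaries did not pass the threshold (adjusted p = 0.215, 0.0872 and 0.108). Of these, dhd and Cmtr1 were also lower in mCherry RNAi than in bam ovaries (adjusted p = 0.0347 and 0.0485). For dhd, CG10802 and Cmtr1 a response to Sxl thus cannot be told from a difference of the mCherry RNAi ovaries, such as their stock. The labels do not describe the stocks. Sxl and CG7755 were lower in both, against 1.17 for independent lists of 1573 and 7 genes (Fisher's exact test, two-sided, p = 0.331). Sxl is the target of the RNAi, so its fall there was set by design and is no response to its own loss. Where it passed the threshold, it is still counted among genes changed in the same direction in both comparisons. With DESeq2, 41 genes were higher in testes and with Sxl RNAi, against 20.9 expected (Fisher's exact p = 1.42e-05), and 47 were lower in both, against 19.1 (Fisher's exact p = 1.30e-09). But 43 were lower in testes and higher with Sxl RNAi, against 20.8 (Fisher's exact p = 2.21e-06), and 22 the reverse, against 19.1 (Fisher's exact p = 0.458). These DESeq2 expectations are over 14032 genes rather than 9415. They count genes that DESeq2 gave no adjusted p (2919 by sex and 3456 with Sxl RNAi) as not called, although these could not be called. This lowers the expected numbers and the p-values of an excess, so the DESeq2 p-values decide nothing about an overlap. The number lower in both was 9 against 4.55 with the length trend removed (Fisher's exact p = 0.0259) and 52 against 29.4 with 2 libraries per comparison left out (Fisher's exact p = 1.31e-05), alternatives chosen after the data were seen. The number higher in both was 1 against 0.0670 under a replicate block (Fisher's exact p = 0.0670). scaf and EMC2A, named after their values were seen, were higher in testes and lower with Sxl RNAi. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of -0.030 and a Spearman correlation of -0.0030. The 741 genes over 1 log2 unit higher in testes had a median log2 fold change of -0.0093 in Sxl RNAi ovaries (camera adjusted p = 0.757, with the test pointing upward), and the 1141 higher in ovaries had 0.056 (camera adjusted p = 0.299). By fry no move on balance in one direction was detected for either set (adjusted p = 0.878 for both), and the test for change in either direction gave adjusted p = 0.000848 and 5.31e-05. The latter asks only whether members change, not whether they change more than other genes. Since 1172 of all 10059 genes had an unadjusted p under 0.05 in the RNAi comparison, it does not single out genes that differ by sex. Leaving out mCherry RNAi replicate 1, or Sxl RNAi replicate 2 or 3, left 1 gene changed in the same direction in both comparisons (Fisher's exact p for genes higher in both 0.147, 0.147 and 0.148), and leaving out mCherry RNAi replicate 3 left 2 (0.0217); CG15930 was among them each time.

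As background, the mCherry RNAi ovaries were compared with the bam ovaries, whose labels name no RNAi; neither group had Sxl knocked down. CG30076, Lasp, CG18853 and CG31683 were near silence in bam ovaries and present in mCherry RNAi ovaries. Lasp, an actin-binding protein gene, stood at 16.5 ± 2.31 against 0.164 ± 0.0169 CPM (adjusted p = 7.60e-05), and CG31683 at 11.2 ± 2.34 against 0.0382 ± 0.0332 CPM. CG30076, chosen here because of its call in the RNAi comparison, had a log2 fold change of 6.06 (adjusted p = 7.40e-05). The lncRNA:CR44289 was lower (2.18 ± 0.331 against 30.9 ± 4.48 CPM), as were CG43797, CG6034 and CG43120, the last of which did not pass the threshold in the fit to all 12 libraries. Among 9940 genes tested, 376 were higher and 231 lower in mCherry RNAi ovaries. The X-linked median did not differ from the autosomal one beyond the test's threshold (camera p = 0.450 at the preset correlation). The total of 607 genes fell to between 153 and 388 when any 1 of the 6 libraries was left out. A member of the Hsp70 family, whose near-identical copies share reads, was also higher, at 130, 23.4 and 10.3 CPM in mCherry RNAi replicates 1, 2 and 3 and at most 0.733 CPM in bam ovaries. This gene did not pass the threshold when mCherry RNAi replicate 2 or any bam ovary was left out (adjusted p between 0.0711 and 0.125, and up to 0.239 over 13 alternatives).

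By list tests in this background comparison, follicle cell genes were lower in mCherry RNAi ovaries (5 of 18 lower, 0 higher; 8 and 1 adjusted over the list alone; camera adjusted p = 0.000805, and adjusted p = 0.862 with an estimated correlation), as were cell cycle genes (0 of 24 past the threshold, 10 lower adjusted over the list alone; camera adjusted p = 0.000805, and adjusted p = 0.862 with an estimated correlation). Heat shock genes (1 of 16 higher, also adjusted over the list alone; camera adjusted p = 0.0245), ovarian niche genes (2 of 17 higher, 3 adjusted over the list alone; camera adjusted p = 0.0349) and JAK-STAT genes (2 of 14 higher, 3 adjusted over the list alone; camera adjusted p = 0.0349) were higher, each with an adjusted p = 0.862 under an estimated correlation, the highest over 12 alternatives for all 5 lists. By fry no list passed in this comparison, the lowest adjusted p being 0.120. The heat shock call was lost without bam ovary replicate 2 (0.107) or 3 (0.0681) or mCherry RNAi replicate 1 (0.237). The niche call was lost without bam ovary replicate 3 (0.327) or mCherry RNAi replicate 1 (0.0764) or 3 (0.0904), and the JAK-STAT call without bam ovary replicate 3 (0.328) or mCherry RNAi replicate 1 (0.114). These 3 calls were also lost with the length trend removed (0.0782 each) and with 2 libraries left out (0.0742 for niche and JAK-STAT genes, 0.211 for heat shock genes), and the niche call under a replicate block (0.0563). Tudor-domain genes gained a call with the length trend removed (0.0355). Other lists gained a call when 1 library was left out. These were hub and cyst cell genes without bam ovary replicate 1 (0.0418) or mCherry RNAi replicate 2 (0.0238), and piRNA pathway (0.0448), Tudor-domain (0.0212) and muscle genes (0.0448) without mCherry RNAi replicate 3.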

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

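The removal of the length trend, the omission of 2 libraries per comparison and the leave-one-out values of X-linked genes were chosen after the data were seen; the other alternatives were planned. Where neither value passed its threshold, a change of sign was not counted as a change. In the sex comparison (3186 genes, 1594 higher in testes and 1592 in ovaries) the replicate block gave 1696 (826 and 870), removing the length trend gave 4848 (2444 and 2404), and a log2 fold change over 1 left 964 higher in testes. In the Sxl RNAi comparison (21 genes, 12 higher and 9 lower) DESeq2 gave 296 (155 and 141), no filter 39 (22 and 17), all 12 libraries in one fit 43 (22 and 21), the replicate block 3 (1 and 2), removing the length trend 42 (22 and 20), and 2 libraries left out 366 (206 and 160). All 21 genes were kept by DESeq2, without a filter, with the length trend removed and with 2 libraries left out, 17 in the 12-library fit and 2 under the block. The libraries left out were picked for standing apart from their groups, which lowers the spread, so the count of 366 is not comparable with 21. In the background comparison (607 genes, 376 higher and 231 lower) DESeq2 gave 1261 (739 and 522), the replicate block 93 (57 and 36), removing the length trend 1429 (837 and 592), 2 libraries left out 1808 (903 and 905), and a log2 fold change over 1 left 136 lower. Genes changed in the same direction by sex and Sxl RNAi (8) became 88 with DESeq2, 17 with all 12 libraries, 1 under the block, 19 with the length trend removed and 105 with 2 libraries left out, while genes changed in opposite directions (2) became 65, 8, 0, 4 and 71. The X-linked difference from autosomes in the RNAi comparison (0.052 on the log2 scale) lost its call with an estimated correlation (p = 0.160). The cause of these changes was not tested, apart from the fewer genes that a fold threshold passes by construction.

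Leaving out 1 replicate gave between 1924 and 3539 genes by sex (882 to 1717 higher in testes, 1025 to 1822 in ovaries), 3 to 23 with Sxl RNAi (1 to 14 higher, 2 to 9 lower), 153 to 388 in the background comparison (89 to 279 higher, 64 to 170 lower), and 1 to 10 genes in the overlap. The X-linked difference ranged from -0.52 to -0.48 by sex, from 0.019 to 0.075 with Sxl RNAi and from -0.049 to 0.0066 in the background. The accessory gland list of the background comparison, with 1 gene in the main fit, had a camera adjusted p of 0.596. With all 12 libraries in one fit its test pointed the other way (camera adjusted p = 0.0346). That fit holds the testes, and 24 of the listed genes passed the filter in the sex comparison. These values thus need not rest on the same genes, and no turn of 1 set of genes is shown. With the length trend removed, the sex comparison lost its calls of the oocyte (adjusted p = 0.0504), sperm storage (0.0504) and hemocyte lists (0.205) and gained early male germline genes (0.00360). With 2 libraries left out it gained these (0.0246) and hub and cyst cell genes (0.00812), as in the 12-library fit (0.0108 and 0.0342), and the RNAi comparison lost the Sxl targets (0.0956). Fat body genes passed by sex under the block (0.0469). With an estimated correlation 8 list calls by sex, 4 with Sxl RNAi and 5 in the background were lost, and none was kept. Replicate numbers did not pair the libraries: same-number deviations correlated at 0.044, -0.39 and -0.60 by sex, -0.13, -0.32 and 0.020 in the RNAi comparison and 0.36, -0.37 and -0.28 in the background, and libraries did not all match best with their own number, so calls lost under the block are not read as weaker effects.

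The X-linked difference by sex kept its direction and its call under each alternative run for it, and CG15930 and CG30076 kept theirs with Sxl RNAi. Over all named genes and alternatives, calls were lost 97 times by sex, 109 times with Sxl RNAi and 8 times in the background, and gained 36 times by sex and 32 times with Sxl RNAi, with the direction kept. In simulations, 36% of 2-fold changes in genes with a mean of at least 5 CPM were recovered by sex and 72% with Sxl RNAi. Smaller differences may thus go undetected. The simulated RNAi set held 180 calls against 21 in the data, which loosens the adjusted threshold, so 72% may overstate the recovery there. The simulated sex set held 134 calls against 3186 in the data, which tightens that threshold, so 36% may understate the recovery by sex. These shares are thus not comparable between the comparisons. DESeq2's 296 genes against 21 leave the number of changed genes open.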

Other observations

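Of the tests below, those of the X-linked genes, apart from that of transcript length, that of the mCherry control stock, those of single genes and that of the Sxl knockdown were chosen only after the result was seen. Sxl RNAi replicate 1 held 0.284% (95% Wilson interval 0.281% to 0.287%) of its counts on gut digestive enzyme genes, against at most 0.0427% in the other RNAi libraries, from a marker list chosen after the data were seen. Antimicrobial peptide genes, also from a list chosen after the data were seen, took 0.0986% (0.0972% to 0.100%) of the counts in bam ovary replicate 3 and at most 0.00649% in the other bam ovaries. In the other groups their share was highest in bam testis replicate 2 (0.0423%), mCherry RNAi replicate 2 (0.0331%) and Sxl RNAi replicate 1 (0.00682%). Among heat shock genes, Hsp23 stood at 3591, 1862 and 357 CPM in mCherry RNAi replicates 1, 2 and 3. In the fit to all 12 libraries, mof, the acetyltransferase of the dosage compensation complex, was higher in Sxl RNAi than in bam ovaries (log2 fold change 1.33, SE 0.14, adjusted p = 0.000392), as were roX1 (1.41, SE 0.28, adjusted p = 0.0146) and TrxT, the testis thioredoxin gene beside dhd (1.37, SE 0.28, adjusted p = 0.0173). roX1 nevertheless stood at 1.96 CPM in Sxl RNAi ovaries and 143 CPM in bam testes. These 3 genes were singled out after their values were seen, and all 3 lie in the X segment discussed below.

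Most of the 12 genes called higher in Sxl RNAi ovaries were X-linked and lay in 1 segment. Without mCherry RNAi replicate 1 or 3, or Sxl RNAi replicate 2 or 3, 1, 2, 1 and 1 higher calls were left. At an unadjusted p under 0.01, 78 X-linked and 121 other genes were higher. Of the X-linked ones, 35 lay among the 410 genes tested in the segment and 43 among the 1301 outside it. The median log2 fold changes there were 0.070 and 0.040. The tests of chance gave a Fisher's exact p of 1.57e-05 for the chromosome of the called genes. For their span the permutation p was 8e-05 over 100000 draws of 9 tested X-linked genes. Both tests used the genes in which the pattern was noticed and take genes as independent, so they cannot exclude chance. A uniform rise of X-linked transcripts, whose median change was 0.050, is argued against. So is a transcript length trend, since 9 of the 9 stayed past the threshold when the trend was removed. A difference on the X chromosome of the mCherry control stock, which the labels do not describe, stays a candidate explanation for some genes. Only 4 of the 9 were also higher than in bam ovaries, under the bound of 5 set for it. A missed threshold does not show that the other 5 did not differ. Of these, Tbh gave 2.12 (SE 0.68, adjusted p = 0.100) over bam ovaries. Bam testes, which entered that fit, spread widely for Tbh (7.90 ± 7.35 CPM). In mCherry RNAi over bam ovaries Tbh gave 0.50 (adjusted p = 0.351), not a fall. With Tbh counted, the bound would not be met. In mCherry RNAi ovaries 4 of the 9 (dhd, Corp, Cmtr1 and APC7) were also lower than in bam ovaries. For CG15930, a gene chosen before the data were examined, the control stock is argued against as the whole cause, since the gene was higher than in bam ovaries by 3.49 (SE 0.20, adjusted p = 7.18e-06). Adjusted by Holm's method over all genes tested, which allows for the picking of single genes, 2 of the 9 passed that contrast, CG15930 (adjusted p = 2.15e-05) and Uros1 (1.05, SE 0.12, adjusted p = 0.0295). The control stock is thus argued against as the whole cause for Uros1 also, which gave 0.08 (SE 0.13, adjusted p = 0.780) in mCherry RNAi over bam ovaries, against 0.98 in Sxl RNAi over mCherry RNAi ovaries. For CG12728 (Holm adjusted p = 0.145) and APC7 it stays open. CG12728 gave -0.20 (SE 0.16, adjusted p = 0.513) in mCherry RNAi over bam ovaries, against 1.27 in Sxl RNAi over mCherry RNAi ovaries, and APC7 gave -1.10 (adjusted p = 0.0249), against 1.99. The X chromosome of the Sxl RNAi stock cannot be told apart from the knockdown, because they come together in every library; 0 X-linked genes other than Sxl were lower. An effect of Sxl itself, which lies inside the segment, also stays open and was not tested.

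Of the 9 genes lower in Sxl RNAi than in mCherry RNAi ovaries, 5 were higher in mCherry RNAi than in bam ovaries. These were CG30076, asRNA:CR45600, CG6912, Dscam3 and Cep290. A difference of the mCherry control stock would give this for these 5. The labels do not describe the stocks. Any other difference between mCherry RNAi and bam ovaries, such as the day of preparation, would give the same and cannot be told apart. Sxl, scaf and CG7755 were also lower in Sxl RNAi than in bam ovaries. The RNAi and background comparisons share the mCherry libraries and had 10 genes called in both, all in opposite directions; independent lists would share 1.25. Chance through these shared libraries is argued against for 2 of the 9 lower genes, CG30076 and asRNA:CR45600, whose rise in mCherry RNAi over bam ovaries passed the threshold by Holm's method over all genes tested (6.06, SE 0.22, adjusted p = 0.000143, and 5.58, SE 0.30, adjusted p = 0.00258). It stays open for the others, with Holm adjusted p = 0.0505 for CG6912 and 0.549 for Dscam3. In 20 simulated sets of unchanged groups the highest number called in both was 0, but no set held more than 2 calls in either comparison, so a number as high as 10 was out of reach and the bound set beforehand decides nothing. Sharing alone gave a correlation across genes of -0.50 between the log2 fold changes, against -0.27 observed, and a covariance of -0.075 against -0.091. For the same 2 of the 9 genes, the Sxl knockdown with no difference between the lines is argued against as the whole cause, since neither mCherry RNAi nor bam ovaries had Sxl knocked down. For the other 7 it stays open, and Sxl, scaf and CG7755 changed by -1.44, -1.76 and -2.88 over mCherry RNAi ovaries and by -1.22, -1.88 and -3.61 over bam ovaries. For the 5 genes named first, the change in Sxl RNAi over bam ovaries was 1.09 (SE 0.36, CG30076), -0.43 (SE 0.59, asRNA:CR45600), 0.06 (SE 0.23, CG6912), -1.05 (SE 0.37, Dscam3) and -0.30 (SE 0.49, Cep290), with adjusted p between 0.115 and 0.935, against -4.96 (CG30076), -2.16 (CG6912), -4.15 (Dscam3) and -2.01 (Cep290) over mCherry RNAi ovaries, where asRNA:CR45600 stood at 7.89 CPM and fell to 0.111 CPM. Whether the knockdown lowers RNA that these RNAi lines hold and bam ovaries lack was not tested, and the 3 mCherry libraries are too few to divide between the comparisons with at least 2 in each.

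Replicates within all 4 groups spread along 1 axis, which held 65.9% of the within-group variance and whose gene loadings had a Spearman correlation of -0.85 with transcript length. Bam ovary 3, bam testis 2, mCherry RNAi 2 and Sxl RNAi 1 lay at the end with more RNA from short transcripts. Removing each library's length trend left 53.3% of the within-group variance and lowered the share of the axis to 40.6% of the variance that remained, or 21.6% of the original variance. The bound set beforehand for the length trend as the cause was under 0.6 of the share, without saying of which variance. The ratio was 0.616 of the remaining variance, which missed it, and 0.328 of the original variance, which met it, so the explanation stays open. Gut and accessory gland markers took at most 0.465% of the counts in these 4 libraries, under the bound set beforehand for tissue from outside the gonad. Their share in bam ovary 3 (0.0323%) and mCherry RNAi 2 (0.0313%) was below that of bam ovary 2 (0.0334%) and mCherry RNAi 3 (0.0439%). In bam testis 2 (0.465%) and Sxl RNAi 1 (0.288%) the share was the highest of the group, against at most 0.101% and 0.0318%. The bound was set beforehand, but the gut markers were chosen after the data were seen. Gut and accessory gland are thus argued against only as 1 cause shared by all 4 groups. Within bam testes and Sxl RNAi ovaries a part played by them stays open. Other outside tissue stays open, because a share of marker counts is not a share of tissue and no other markers entered the bound. Antimicrobial peptide genes took their highest share of each group in these same 4 libraries. No biological explanation was tested.

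With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each comparison 1 split, the real one, reached its count: 3186 genes by sex, 21 with Sxl RNAi and 607 in the background, where the highest other split gave 0.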
